A study of Homo sapiens with 42 samples.

How the data were processed

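RNA from 42 frozen biopsies of transformed follicular lymphoma was measured on single-colour Affymetrix HG-U133 Plus 2 arrays with 54675 probe sets, in 1 group with no contrast in the labels. The deposited table holds log2 values, 1 column per array. The authors' signals were computed with MAS5, per the submitters' processing notes. The log2 scale, a floor at 3.32 (the log2 of 10) and a quantile normalization between arrays are inferred from the deposited log2 values, which share their median (4.73) and 75th percentile (6.54) in every array. The scaling target, the software version and any filter are not given in the sources used here. Because values were forced to the same median and 75th percentile, an array with poor RNA shows no difference in these. The share of probe sets at the array's lowest value still ranged from 12.7% to 39.3%. Raw scanner files were not used here.

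Gene names came from the platform annotation given with the values: 41097 probe sets had 1 gene symbol, 1801 several, and 11777 none or were not listed. Of 41032 kept after leaving out control probe sets, XIST, TSIX and genes of the Y chromosome, 40978 matched the GRCh38.p14 gene table by Entrez number, and 0 symbols needed an update. That table was used for names and for which genes neighbour each other. Genes without a probe set of their own were not analysed here. Values below the pooled 20th percentile (3.33) were raised to it. For each of 19740 genes the probe set of highest mean was used, and 14798 genes above the pooled median (4.73) in at least 9 arrays were tested. Of 270 named genes 142 had another probe set above this filter; its highest r with the one used was over 0.5 for 113 genes and under 0.3 for 12, and such genes are marked in the text where they are named among the largest changes.

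Gene lists were fixed before the data were examined: proliferation, MYC targets, germinal centre B cell, activated B cell, B cell, T cell, cytotoxic cell, macrophage, follicular dendritic cell, stroma, endothelial, plasma cell, MHC class I, MHC class II, NF-kB targets, p53 targets, interferon response, oxidative phosphorylation, glycolysis, immediate early genes, epithelial, neutrophil, erythroid, adipocyte, skeletal muscle, and lymphoma and transformation genes. A list score is the mean z score of its tested members over the arrays, for lists with at least 4 of them; the skeletal muscle list had 2 (mean log2 level 4.10 ± 0.63, SD over 42 arrays) and was not tested. Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend) on the proliferation score, the activated B cell minus germinal centre B cell score, and the T cell score, each scaled to an SD of 1. A member was fitted against the score without it. The threshold was an adjusted p of 0.05 (Benjamini-Hochberg). List shifts were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. Correlations had two-sided permutation tests with 100000 permutations. Windows of 21 neighbouring genes were compared with 10000 random windows.

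Named genes were, per score, the 12 of largest positive and 12 of largest negative slope past the threshold outside the score's lists, up to 4 members of smallest p per list, the lymphoma genes of a relation or fit, the 24 genes of highest SD, and the anchors of the windows. Other named members of windows were chosen after their values were seen.

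The procedures were tested on simulated data. For the score fits over 14798 genes with 42 arrays, 7, 31, 46 and 49 of 50 genes were recovered at slopes of 0.25, 0.5, 0.75 and 1, with 8 false calls among 14598 unchanged genes. Here each gene's values were shuffled over the arrays on their own, and the score was random. The real scores are made of correlated genes of the same arrays, so the false calls of the real fits cannot be read from this. A correlation of 0.6 passed an unadjusted p of 0.05 in 98 of 100 simulations and a correlation of 0 in 4 of 100. For the windows, 20 of 20 with a shared factor that gave a mean r of 0.36 were recovered, in data where each gene was shuffled on its own. Weaker shared variation was not simulated.

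Alternatives fixed before the data were examined were another quantile normalization, no floor, no filter or a stricter filter (21 arrays), the mean of all probe sets, leaving out probe sets ending in _x_at, leaving out 5 arrays by their title number, the 3'/5' ratio or cell type scores as covariates, leaving out the 2 farthest arrays, the median in place of the mean of z scores, ranks, 1000 variable genes, and 5 neighbours on each side. Added after seeing the data were leaving out the 5 arrays of lowest median correlation, leaving out the array with a high cre control, array quality (the median correlation) with the 3'/5' ratio as covariates, and leaving out each array in turn. Scores of 100 random gene sets of the same sizes, drawn outside the score's lists, were also fitted after seeing the data. The quantile normalization moved nearly nothing, since the values were already normalized this way. Figures were drawn with matplotlib 3.10.9.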

Results

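Gene expression was measured in 42 frozen tumour biopsies of transformed follicular lymphoma, a germinal centre B cell lymphoma that has progressed from an indolent to an aggressive disease. Each biopsy was hybridized to 1 Affymetrix HG-U133 Plus 2 array, a single-colour array whose probe sets each report the signal of a transcript. The labels gave 1 group and no contrast, so the tumours were compared along continuous scores of gene lists fixed before the data were examined, and no tumour was put into a class. The series belongs to a study of copy number changes in transformation, and copy number itself was not analysed here. The labels do not say whether the arrays came from separate patients, so p-values measure the spread between these 42 arrays. Of 19740 genes with a probe set, 14798 were above the pooled median signal in at least 9 arrays and were tested. The number of arrays limits the precision of each value.

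Signal levels differed little in overall distribution, with a median of 4.73 and a 75th percentile of 6.54 (log2) in every array. The arrays did differ in how well they correlated with each other. The median Pearson r of an array with the other arrays was 0.870 ± 0.054 (SD, n = 42) and ranged from 0.616 to 0.906. This value was 0.745 ± 0.084 (SD, n = 5) in the 5 lowest arrays and 0.887 ± 0.012 (SD, n = 37) in the other 37. The 5 lowest arrays also had a higher 3'/5' signal ratio of the GAPDH and ACTB control probe sets (2.32 ± 0.27 against 1.67 ± 0.48, log2, SD). Their Bacillus control probe sets were brighter as well (9.85 ± 0.88 against 7.50 ± 0.50). The leading principal component held 15.7% of the variance. Its absolute Pearson r with the median correlation of the array was 0.95 (permutation p = 1e-05, the smallest that 100000 permutations can give; adjusted p = 1.65e-04 over the components and measures tested). Its absolute Spearman rho was 0.56 (permutation p = 1.80e-04), and r was 0.82 without the 2 farthest arrays. Both measures come from the same values, and an array unlike the others tends to stand out in both. The p-values are therefore no independent evidence that quality is the leading difference. Because 5 arrays stood apart, list shifts that differed in the 37 other arrays are named beside the gene groups.

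The 24 genes of highest SD between tumours included immunoglobulin genes, 2 HLA class II genes and genes of several cell types. IGHM, the constant region of the IgM heavy chain, had the highest SD, 3.42 on the log2 scale (n = 42). Its mean was 9.38, and its 10th and 90th percentiles were 4.77 and 13.43. RARA, described below, came next. HLA-DRB4 (SD 3.35), a gene carried by only some HLA haplotypes, HLA-DQA1 (3.22) and the immunoglobulin heavy locus IGH (2.95) followed. FDCSP, secreted by follicular dendritic cells, had an SD of 2.87, and JCHAIN, the joining chain of IgM and IgA, of 2.52. LTF (lactoferrin, 2.64), ORM1 (an acute phase protein, 2.59), FABP4 (the fatty acid carrier of adipocytes and capillaries, 2.54) and CHIT1 (chitotriosidase of activated macrophages, 2.30) varied over a similar range. Among B cell genes, the SD was 2.41 for TCL1A, 2.43 for its neighbour TCL1B, 2.36 for the germinal centre serpin SERPINA9 and 2.34 for the pro-apoptotic gene BIK. EPCAM, an epithelial adhesion molecule, had a mean of 4.83 and was above the pooled median in 13 arrays. RARA had an SD of 3.35. This value rests on 1 probe set, whose r with the gene's 3 other probe sets ranged from -0.41 to 0. The rest of the 24 genes of highest SD were CFAP251, RASSF6, HTR3A, ZNF595, CCL22, SFRP4, MACROD2 and CCDC85A, with SDs from 2.29 to 2.51.

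Cell type lists were over-represented among the 500 most variable genes. The stroma list led with 12 of its 17 tested genes, where 0.57 were expected by chance (one-sided Fisher's exact test, adjusted p = 2.58e-13 over 25 lists). Among them were the matrix genes POSTN, DCN, COL3A1, COL1A1 and FN1. Macrophage genes followed with 7 of 12 (adjusted p = 4.12e-07), namely VSIG4, CD163, C1QB, C1QA, MRC1, MSR1 and CD14. The follicular dendritic cell list had 4 of 6 (adjusted p = 1.53e-04). Cytotoxic cell genes had 5 of 12 (GNLY, GZMB, GZMH, KLRB1 and NKG7, adjusted p = 1.75e-04). B cell genes had 5 of 15 (TCL1A, VPREB3, FCRL1, BANK1 and SPIB, adjusted p = 4.89e-04). The erythroid (3 of 4), plasma cell (4 of 12), germinal centre B cell (4 of 13), immediate early (4 of 13), neutrophil (3 of 7), adipocyte (2 of 4), interferon response (3 of 12), T cell (3 of 13), NF-kB target (3 of 14) and epithelial (2 of 6) lists also passed, with adjusted p from 6.23e-04 to 0.0260. The MYC target, endothelial, MHC class I, p53 target, oxidative phosphorylation and glycolysis lists had 0 genes among the 500. The activated B cell (2 of 17), MHC class II (1 of 10), proliferation (1 of 25, MKI67) and lymphoma gene lists (2 of 33, FCGR2B and BCL2) did not pass. In the 37 arrays the T cell and NF-kB target lists did not pass. Fisher's test treats the genes of a list as independent. Within a list they were correlated, with an estimated correlation of 0.72 for stroma and 0.56 for macrophage genes in the fit on proliferation. These p-values may therefore be too small, and they do not measure the spread between tumours.

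Along the proliferation score the largest rises outside the score included genes of mitosis and DNA replication, and 10 of 13 MYC target genes and 7 of 13 glycolysis genes rose. Smaller shares of the T cell (4 of 13) and endothelial (1 of 12) lists fell. A change is given as the log2 slope per 1 SD of the score with its SE (n = 42), from limma with Benjamini-Hochberg adjustment. KIFC1, a mitotic kinesin, rose by 1.01 ± 0.14 (adjusted p = 5.25e-07), a 2.01-fold difference per SD. The replication factors CDC45 (0.96) and MCM10 (0.93) rose as well. So did the spindle and kinetochore genes DLGAP5 (0.96), CDCA8 (0.95), NDC80 (0.85) and CENPE (0.85) and the cytokinesis gene ANLN (0.92). The transcription factors MYBL2 (0.95), FOXM1 (0.83) and E2F7 (0.83) and the ubiquitin ligase receptor DTL (0.87) rose too. E2F7 had a second probe set with an r of only 0.14 with the one used. Among the 12 largest falls outside the score were those of KLRB1 (-0.91 ± 0.20), a receptor of natural killer and T cells, the B cell chemokine CXCL13 (-0.86 ± 0.23), the IL-7 receptor IL7R (-0.80 ± 0.19) and the mannose receptor MRC1 (-0.76 ± 0.22). The antioxidant enzyme GPX3 (-0.85), the matrix genes EFEMP1 (-0.79) and MGP (-0.76), and CCDC3 (-0.81), PLAC8 (-0.76), KCNJ2 (-0.76), AOX1 (-0.74) and DDX60L (-0.73) fell as well. AOX1 also had another probe set with an r of 0.14.

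In all, 1477 genes rose and 556 fell along the proliferation score (72.7% rising). Without the 5 arrays of low correlation 897 rose and 640 fell (58.4% rising), with 1073 genes shared with the fit of all arrays. Leaving out replicate 5 alone, 1 of those 5 arrays, gave 656 rising and 429 falling genes (60.5% rising). Of 100 scores made from random gene sets of the same size, 45 had at least as many associated genes as the proliferation score when all genes were fitted (median 1533.5), so the count alone does not set this score apart.

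Of 13 MYC target genes 10 rose with proliferation (11 adjusted over the list alone), and 5 of 13 rose in the 37 arrays. Among the 10 were the ribosome biogenesis genes NOP16 (0.41 ± 0.10) and FBL (0.39 ± 0.10), the RNA polymerase I subunit POLR1B (0.53 ± 0.11) and the spermidine synthase SRM (0.50 ± 0.12). The list shifted up against other genes (camera, adjusted p = 2.25e-05; adjusted p = 0.220 with an estimated correlation). Of 13 glycolysis genes 7 rose (8 adjusted over the list alone) and 5 rose in the 37 arrays. Among the 7 were LDHA (0.33 ± 0.06), GPI (0.41 ± 0.10), PGAM1 (0.27 ± 0.06) and GAPDH (0.21 ± 0.05). The glycolysis list shifted up (adjusted p = 8.25e-04; adjusted p = 0.534 with an estimated correlation). Given array quality and the 3'/5' ratio, the r of the glycolysis with the proliferation score went from 0.52 to 0.36 and did not pass (permutation test, adjusted p = 0.0653). That of the MYC target score went from 0.68 to 0.59 and passed (adjusted p = 7.60e-04). Of 13 germinal centre B cell genes 3 rose (4 adjusted over the list alone), GCSAM (0.55 ± 0.18), S1PR2 (0.46 ± 0.15) and IRAG2 (0.45 ± 0.15), and 0 rose in the 37 arrays. Their list shifted up (adjusted p = 0.0278; adjusted p = 0.542 with an estimated correlation). Of 11 oxidative phosphorylation genes 2 rose, COX5A (0.23 ± 0.05) and ATP5F1B (0.16 ± 0.05), 3 adjusted over the list alone, and the list did not shift (adjusted p = 0.0848). In the 37 arrays it shifted up with the preset correlation and did not with an estimated correlation. POLR1B, NOP16, SRM and ATP5F1B did not pass in the 37 arrays.

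Among genes of other cells, 4 of 13 T cell genes fell (5 adjusted over the list alone), and 8 of 13 fell in the 37 arrays. The 4 were CD3D (-0.73 ± 0.16), IL7R, CD2 (-0.65 ± 0.16) and TRBC1 (-0.60 ± 0.16). The T cell list shifted down (adjusted p = 2.25e-05; adjusted p = 0.534 with an estimated correlation). The endothelial adhesion molecule PECAM1 (-0.56 ± 0.10) fell as 1 of 12 endothelial genes (1 adjusted over the list alone), and 2 of 12 fell in the 37 arrays. MRC1 and the growth factor receptor CSF1R (-0.47 ± 0.14) fell as 2 of 12 macrophage genes, and KLRB1 as 1 of 12 cytotoxic cell genes (2 and 1 adjusted over the list alone). CXCL13 fell as 1 of 6 follicular dendritic cell genes (2 adjusted over the list alone). FBN1 (-0.57 ± 0.15) and PDGFRB (-0.42 ± 0.15) fell as 2 of 17 stroma genes (1 adjusted over the list alone). Of 11 MHC class I genes 3 fell (4 adjusted over the list alone), the trans-activator NLRC5 (-0.45 ± 0.13), HLA-F (-0.27 ± 0.08) and HLA-E (-0.26 ± 0.09), and 5 fell in the 37 arrays. In the neutrophil list 0 of 7 genes passed in limma, and 2 had an unadjusted p under 0.05. These 7 lists shifted down at adjusted p from 8.72e-04 to 0.0278. With an estimated correlation, adjusted p = 0.534 for the macrophage, follicular dendritic cell, endothelial and MHC class I lists and adjusted p = 0.542 for the cytotoxic cell, stroma and neutrophil lists. FBN1, PDGFRB, CXCL13 and MGP did not pass in the 37 arrays.

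Of 33 lymphoma and transformation genes 5 rose and 1 fell with proliferation (5 and 3 adjusted over the list alone). The histone methyltransferase EZH2 (0.43 ± 0.07), the cyclin-dependent kinase CDK4 (0.46 ± 0.09) and CDKN2A (0.59 ± 0.14), which encodes an inhibitor of that kinase, rose. BCL11A (0.44 ± 0.13) and the nuclear exporter XPO1 (0.15 ± 0.05) rose as well, and the anti-proliferative gene BTG1 fell (-0.25 ± 0.07). The slope of MYC was 0.10 ± 0.14 (adjusted p = 0.705) and that of BCL2 was -0.22 ± 0.22 (adjusted p = 0.564). Of 18 p53 target genes BAX rose (0.45 ± 0.12) and SESN1 fell (-0.61 ± 0.11), with 2 and 1 adjusted over the list alone. KLF6 (-0.28 ± 0.09) fell as 1 of 13 immediate early genes and HLA-DPB1 (-0.43 ± 0.15) as 1 of 10 MHC class II genes (1 and 0 adjusted over the list alone). In the B cell, activated B cell, plasma cell, NF-kB target, interferon response, epithelial, erythroid and adipocyte lists 0 genes passed in limma, and 0 to 3 per list had an unadjusted p under 0.05. The lymphoma, p53 target, immediate early and MHC class II lists and these 8 did not shift (adjusted p from 0.0721 to 0.822). In the 37 arrays the interferon response, immediate early, plasma cell, MHC class II and NF-kB target lists shifted down with the preset correlation, and none of these 5 did with an estimated correlation. CDKN2A, XPO1, BAX and HLA-DPB1 did not pass in the 37 arrays.

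**Figure D1:**
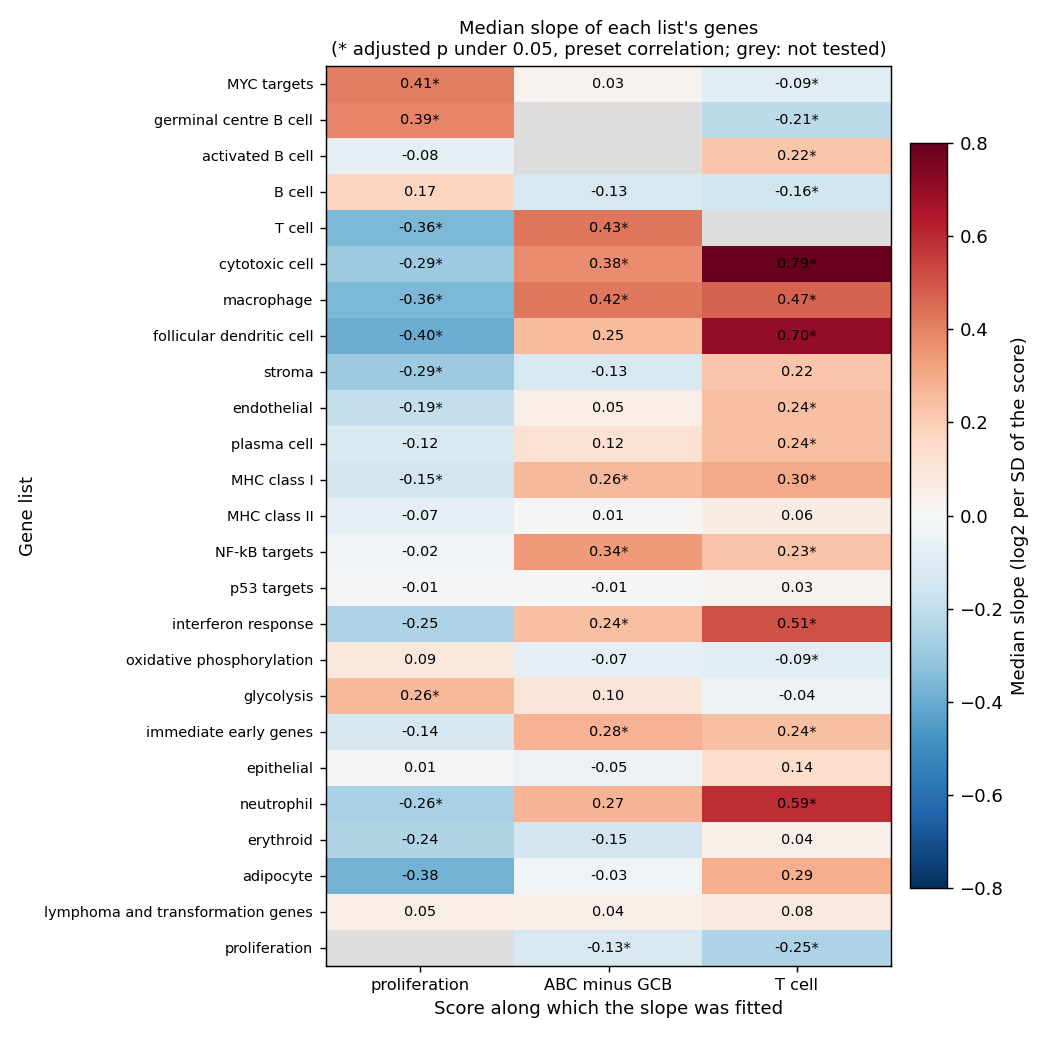
Median slope of each gene list (rows) along the 3 scores (columns), in log2 units per 1 SD of the score over 42 arrays; red is higher and blue lower with a higher score, a star marks adjusted p under 0.05 with the preset correlation, and grey cells were not tested. The cytotoxic cell list has the largest median slope, 0.79 along the T cell score, and the MYC target list reaches 0.41 along the proliferation score.

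The score of activated B cell minus germinal centre B cell genes separates expression programmes used to describe the cell of origin of large B cell lymphoma, and it served here as a continuous axis. Tumours with a higher score expressed more of the lymph node homing receptor CCR7 (1.06 ± 0.18) and the IgM Fc receptor FCMR (1.20 ± 0.25). They also expressed more of the Fc receptor-like gene FCRL5 (0.98 ± 0.25) and the IL-2 receptor chain IL2RB (0.86 ± 0.13). They expressed less of the pre-B cell receptor component VPREB3 (-1.32 ± 0.27), the meiotic cohesin STAG3 (-1.28 ± 0.27) and the protease inhibitor SPINK2 (-1.24 ± 0.25). TOX2, of the TOX family of transcription factors, had the largest rise outside the score, 1.30 ± 0.21 (limma, adjusted p = 1.14e-04). The genes RUBCNL (1.23), CHST2 (0.98), NRROS (0.94), CHI3L1 (0.92), LINC01943 (0.91), SLA (0.91) and the myeloid nuclear antigen MNDA (0.90) also rose. KCNK12 (-1.11) and HTR3A (-1.08), which encode ion channels, fell, and so did S100Z (-1.07), SYBU (-1.02), SYTL4 (-1.02), ACY3 (-0.98), LYPD6B (-0.96), ZFAND4 (-0.94) and PKHD1L1 (-0.94).

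Along this score 207 genes rose and 187 fell, and 280 rose and 290 fell without the 5 arrays of low correlation. With the T cell, macrophage and stroma scores as covariates 96 rose and 108 fell. Of the 207 rising genes 98 also rose with the T cell score, where independent lists would share 11.7. Of the 187 falling genes 31 also fell with the T cell score, where 2.8 would be shared. Both overlaps come from fits on the same arrays. Of 100 differences between random gene sets of the same sizes, 32 had at least as many associated genes (median 102). The members of the score were each fitted against the score without it. Among those that moved with it were BATF (0.90 ± 0.13), CCDC50 (0.81 ± 0.11), IRF4 (1.01 ± 0.20), SERPINA9 (-1.59 ± 0.26) and MYBL1 (-1.43 ± 0.22, with another probe set at an r of 0.08). Not all members passed, for example BCL6 (-0.32 ± 0.10, limma, adjusted p = 0.0855).

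Of the lists, NF-kB targets and MHC class I shifted up along the score with the preset correlation and not with an estimated correlation, and MHC class II did not shift. Of 14 NF-kB target genes 3 rose (10 adjusted over the list alone), the apoptosis regulators CFLAR (0.82 ± 0.12) and BCL2A1 (0.72 ± 0.20) and TNFAIP2 (0.58 ± 0.16). The list shifted up (camera, adjusted p = 1.28e-07; adjusted p = 0.152 with an estimated correlation). Of 11 MHC class I genes 4 rose (7 adjusted over the list alone), NLRC5 (0.64 ± 0.12), HLA-B (0.32 ± 0.06), the peptide transporter TAP1 (0.40 ± 0.09) and HLA-C (0.26 ± 0.06). The class I list shifted up (adjusted p = 1.67e-07; adjusted p = 0.152 with an estimated correlation). CD28 (0.65 ± 0.18) and CD6 (0.66 ± 0.19) rose among 13 T cell genes (7 rose and 1 fell adjusted over the list alone), and 0 rose and 1 fell in the 37 arrays. The cytotoxic granule genes PRF1 (0.62 ± 0.17) and GZMB (0.83 ± 0.24) rose among 12 cytotoxic cell genes (4 adjusted over the list alone). Of 12 macrophage genes 0 passed in limma (4 rose adjusted over the list alone, and 7 had an unadjusted p under 0.05). These 3 lists shifted up at adjusted p of 1.42e-05 to 3.91e-05, and adjusted p = 0.399 for each with an estimated correlation. CHI3L1, TNFAIP2, CD28, CD6 and PRF1 did not pass in the 37 arrays.

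Of 12 interferon response genes GBP1 (0.68 ± 0.18) rose (1 adjusted over the list alone), and the list shifted up (adjusted p = 0.0437; adjusted p = 0.732 with an estimated correlation). Of 13 immediate early genes 0 passed in limma, also adjusted over the list alone, and 5 had a positive slope with an unadjusted p under 0.05. The list shifted up (adjusted p = 0.0019; adjusted p = 0.637 with an estimated correlation). Of 25 proliferation genes 0 passed in limma, also adjusted over the list alone, and 6 had a negative slope with an unadjusted p under 0.05. That list shifted down (adjusted p = 1.43e-04; adjusted p = 0.677 with an estimated correlation). SLAMF7, a plasma cell and lymphocyte surface receptor, rose by 0.81 ± 0.18 as 1 of 12 plasma cell genes (2 rose and 1 fell adjusted over the list alone). VPREB3 was the 1 of 15 B cell genes that fell (1 rose and 3 fell adjusted over the list alone). Of 32 lymphoma genes 0 passed in limma (3 rose and 1 fell adjusted over the list alone, and 10 had an unadjusted p under 0.05). The slopes were 0.35 ± 0.10 for RB1, 0.38 ± 0.12 for PIM1 and -0.27 ± 0.08 for GNA13, which passed in the 37 arrays. BCL6, a member of the score and so not among the 32, had a slope of -0.32 ± 0.10 and also passed only in the 37 arrays. The MYC target, B cell, follicular dendritic cell, stroma, endothelial, plasma cell, MHC class II, p53 target, oxidative phosphorylation, glycolysis, epithelial, neutrophil, erythroid, adipocyte and lymphoma gene lists did not shift (adjusted p from 0.0514 to 0.905). In the 37 arrays, where 3 of 15 B cell genes fell, the B cell list shifted down with the preset correlation and did not with an estimated correlation. In those without the B cell, plasma cell and lymphoma lists 0 genes passed in limma, and 0 to 3 per list had an unadjusted p under 0.05. Adjusted over the list alone, 1 follicular dendritic cell gene rose.

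Along the T cell score 11 of 12 cytotoxic cell genes and 4 of 6 follicular dendritic cell genes rose. In all arrays these are the list shifts that held with an estimated correlation. In the 37 arrays only the cytotoxic cell list held (camera, adjusted p = 0.0345, against 0.0854 for the follicular dendritic cell list). Of the macrophage list 6 of 12 and of the MHC class I list 6 of 11 genes rose, and 5 of 25 proliferation genes fell. CTLA4, an inhibitory T cell receptor, rose by 1.17 ± 0.13 per SD (adjusted p = 1.23e-08), the kinase ZAP70 by 1.14 ± 0.14, the T cell developmental factors BCL11B by 1.03 ± 0.08 and THEMIS by 1.04 ± 0.14, and SIRPG by 1.10 ± 0.13. The chemokines CXCL13 (1.23 ± 0.20), made by follicular dendritic cells and follicular helper T cells, and CCL21 (1.02 ± 0.30), made by lymph node stroma, rose, as did PLAC8 (1.31), CLU (1.24), LTF (1.19), HS3ST3B1 (1.12) and CST7 (1.06). HS3ST3B1 had another probe set with an r of -0.24. The largest falls were those of FAM81A (-0.79 ± 0.16), the chaperone CLGN (-0.76 ± 0.21), BCAS4 (-0.76 ± 0.16), GCHFR (-0.76 ± 0.17) and MUC16 (-0.75 ± 0.22). CCDC138 (-0.74), PKHD1L1 (-0.66), MED12L (-0.61), DNAH6 (-0.61), the CTP synthase CTPS2 (-0.60), SERHL2 (-0.59) and the adaptor TRAF4 (-0.58) fell as well. MED12L had another probe set with an r of 0.21. CCL21, CLGN, PKHD1L1, DNAH6 and SERHL2 did not pass in the 37 arrays.

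Along the T cell score 838 genes rose and 220 fell (79.2% rising), and 1019 rose and 659 fell (60.7% rising) without the 5 arrays of low correlation. Leaving out replicate 5 gave 978 rising and 448 falling genes, replicate 30 gave 578 and 113, and replicate 32 gave 599 and 110. Leaving out the 2 arrays farthest from the median score gave 351 and 31. Of 100 scores made from random gene sets of the same size, 46 had at least as many associated genes as the T cell score (median 597). Of the genes that fell with proliferation 192 rose with the T cell score, where independent lists would share 31.5. Of those that rose with proliferation 116 fell with the T cell score, where 22 would be shared. These overlaps come from the same arrays and from correlated scores.

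Of 12 cytotoxic cell genes 11 rose (12 adjusted over the list alone), including GZMK (0.99 ± 0.15), KLRB1 (1.01 ± 0.19), CD8A (0.84 ± 0.14) and PRF1 (0.74 ± 0.16). The list shifted up (camera, adjusted p = 3.39e-13; adjusted p = 0.0148 with an estimated correlation). Of 6 follicular dendritic cell genes 4 rose (6 adjusted over the list alone), CXCL13, CLU, the adhesion molecule VCAM1 (0.52 ± 0.11) and the complement receptor CR1 (0.45 ± 0.12). Their list shifted up (adjusted p = 1.77e-06; adjusted p = 0.0148 with an estimated correlation, a call not kept in the 37 arrays). Of 11 MHC class I genes 6 rose (7 adjusted over the list alone), among them HLA-E (0.44 ± 0.07), HLA-F (0.40 ± 0.06), HLA-B (0.34 ± 0.06) and HLA-C (0.33 ± 0.05). The class I list shifted up (adjusted p = 1.49e-07; adjusted p = 0.0673 with an estimated correlation). Of 12 macrophage genes 6 rose (8 adjusted over the list alone), for example the complement gene C1QB (0.87 ± 0.24), CD14 (0.69 ± 0.18) and AIF1 (0.47 ± 0.09). The macrophage list shifted up (adjusted p = 2.89e-06; adjusted p = 0.203 with an estimated correlation). Of 7 neutrophil genes 2 rose (6 adjusted over the list alone), FPR1 (0.62 ± 0.18) and CXCR2 (0.46 ± 0.14), and 5 of 7 rose in the 37 arrays. The neutrophil list shifted up (adjusted p = 3.61e-04; adjusted p = 0.203 with an estimated correlation).

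Of 12 interferon response genes GBP1 (0.80 ± 0.16), IFIT2 (0.55 ± 0.16) and IFIT3 (0.54 ± 0.16) rose (8 adjusted over the list alone), and 6 of 12 rose in the 37 arrays. The list shifted up (adjusted p = 2.06e-05; adjusted p = 0.245 with an estimated correlation). The NF-kB targets TNFAIP2 (0.78 ± 0.15), TNFAIP3 (0.51 ± 0.12) and CCL4 (0.67 ± 0.19) rose as 3 of 14 (3 adjusted over the list alone). CCND2 (0.73 ± 0.13) and ETV6 (0.51 ± 0.11) rose as 2 of 17 activated B cell genes, and PRDM1 (0.76 ± 0.17) and SLAMF7 (0.77 ± 0.19) as 2 of 12 plasma cell genes (2 each adjusted over the list alone). PECAM1 (0.49 ± 0.11) rose as 1 of 12 endothelial genes (2 adjusted over the list alone). Of 13 immediate early genes 0 passed in limma, also adjusted over the list alone, and 6 had an unadjusted p under 0.05. These 5 lists shifted up (adjusted p from 0.0029 to 0.0117). With an estimated correlation, adjusted p = 0.345 for the NF-kB, activated B cell and immediate early lists, adjusted p = 0.252 for the plasma cell list and adjusted p = 0.305 for the endothelial list.

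The proliferation list shifted down along the T cell score (adjusted p = 3.15e-10; adjusted p = 0.203 with an estimated correlation). Of its 25 genes 5 fell (12 adjusted over the list alone), and 12 of 25 fell in the 37 arrays. Among the 5 were NUSAP1 (-0.39 ± 0.09), MCM4 (-0.44 ± 0.11), CDK1 (-0.43 ± 0.13) and PCNA (-0.22 ± 0.07). STAP1 (-0.55 ± 0.16) fell as 1 of 13 germinal centre B cell genes and ATP5MC3 (-0.22 ± 0.07) as 1 of 11 oxidative phosphorylation genes (2 and 1 adjusted over the list alone). Of 15 B cell and 13 MYC target genes 0 passed in limma, also adjusted over the lists alone, and 5 and 2 had an unadjusted p under 0.05. In the 37 arrays 3 of 15 and 8 of 13 fell. These 4 lists shifted down (adjusted p from 0.0022 to 0.0190). With an estimated correlation, adjusted p = 0.252 for the germinal centre and oxidative phosphorylation lists, adjusted p = 0.345 for the B cell list and adjusted p = 0.354 for the MYC target list. The oxidative phosphorylation list did not shift in the 37 arrays.

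Among 33 lymphoma genes 4 rose and 1 fell (4 and 1 adjusted over the list alone), and 5 rose and 4 fell in the 37 arrays. The risers were the class I chain B2M (0.17 ± 0.04), PRDM1, TNFAIP3 and TNFRSF14 (0.35 ± 0.11), a receptor that takes part in signalling between B and T cells, and BCL11A fell (-0.54 ± 0.12). CDH1 rose as 1 of 6 epithelial genes (0.67 ± 0.19) and FAS as 1 of 18 p53 targets (0.45 ± 0.12), each also adjusted over the list alone. CDK1, CR1, ATP5MC3 and CDH1 did not pass in the 37 arrays. The stroma, MHC class II, p53 target, glycolysis, epithelial, erythroid, adipocyte and lymphoma gene lists did not shift (adjusted p from 0.0717 to 0.934). In the stroma, MHC class II, glycolysis, erythroid and adipocyte lists 0 genes passed in limma, also adjusted over the lists alone, and 0 to 3 per list had an unadjusted p under 0.05.

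The scores of 20 lists were correlated with each other to ask which cell types and programmes varied together. Of 190 pairs, 33 were positively and 15 negatively correlated past the threshold by Pearson's r (two-sided permutation test, Benjamini-Hochberg over the 190 pairs), 43 of these 48 also by Spearman's rho. Of these pairs, 37 passed again in the 37 arrays of higher correlation and 33 without the 2 farthest arrays, where 21 of all pairs were positively correlated. Given the T cell, macrophage and stroma scores, 9 pairs were positively and 3 negatively correlated among those without these lists, against 20 and 10 with no scores given. T cell and cytotoxic cell scores rose together (r = 0.70, adjusted p = 3.17e-04, with permutation p = 1e-05, the smallest that can be given; rho = 0.67, adjusted p = 2.71e-04; r = 0.63 without the 2 farthest arrays and 0.74 in the 37 arrays). T cell and follicular dendritic cell scores rose together as well (r = 0.69, permutation p = 2e-05, adjusted p = 3.80e-04; rho = 0.70, adjusted p = 2.71e-04; 0.71 without the 2 farthest and 0.65 in the 37 arrays). Activated B cell and NF-kB target scores were positively correlated (r = 0.68, permutation p = 1e-05, adjusted p = 3.17e-04; rho = 0.68, adjusted p = 2.71e-04; 0.67 and 0.63), and so were stroma and endothelial scores (r = 0.64, permutation p = 2e-05, adjusted p = 3.80e-04; rho = 0.67, adjusted p = 2.71e-04; 0.57 and 0.68). Proliferation rose with MYC targets (r = 0.68, permutation p = 1e-05, adjusted p = 3.17e-04; rho = 0.55, adjusted p = 0.0023; 0.53 and 0.63).

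Germinal centre and activated B cell scores were opposed (r = -0.62, permutation p = 1e-05, adjusted p = 3.17e-04; rho = -0.61, adjusted p = 2.71e-04; -0.58 without the 2 farthest and -0.73 in the 37 arrays). The B cell score was lower where the macrophage score was higher (r = -0.61, permutation p = 6e-05, adjusted p = 8.77e-04; rho = -0.53, adjusted p = 0.0042; -0.54 and -0.70). The oxidative phosphorylation score was lower where the immediate early score was higher (r = -0.56, permutation p = 1e-04, adjusted p = 0.0014; rho = -0.52, adjusted p = 0.0053; -0.42 and -0.58). Proliferation and T cell scores were inversely correlated (r = -0.42, permutation p = 0.0052, adjusted p = 0.0270; rho = -0.47, adjusted p = 0.0128; -0.53 and -0.55). Given the 3'/5' ratio alone this correlation (r, proliferation with T cell, of -0.345) did not pass, and given array quality and the ratio together it passed (r = -0.52). Given the mean of the macrophage, follicular dendritic cell, stroma and endothelial scores r was -0.21 (permutation p = 0.184).

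**Figure D2:**
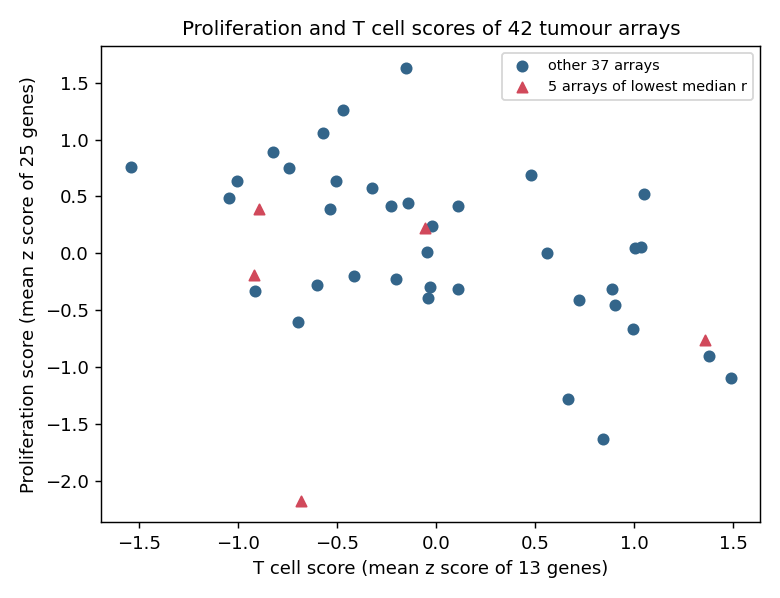
Proliferation score (vertical axis, mean z score of 25 genes) against T cell score (horizontal axis, mean z score of 13 genes) in 42 arrays, each point 1 array, with triangles for the 5 arrays of lowest median r and circles for the other 37. The points run from upper left to lower right, with r = -0.42 in all arrays, -0.55 in the 37, and -0.21 in all arrays given the mean of 4 other cell type scores.

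Of 28 relations of single genes fixed before the data were examined, 26 were tested, and 13 were positive and 0 negative past the threshold (Benjamini-Hochberg over the 26; 14 had an unadjusted p under 0.05). EZH2 followed the proliferation score (r = 0.71, adjusted p = 6.50e-05, with permutation p = 1e-05, the smallest that can be given; rho = 0.66, adjusted p = 5.20e-05; r = 0.67 without the 2 farthest arrays and 0.72 in the 37 arrays). TNFAIP3, an inhibitor of NF-kB that is itself induced by it, followed the other NF-kB targets (r = 0.69, permutation p = 1e-05, adjusted p = 6.50e-05; rho = 0.73, adjusted p = 5.20e-05; 0.68 and 0.70). CIITA, the master regulator of MHC class II, followed the class II genes (r = 0.65, permutation p = 1e-05, adjusted p = 6.50e-05; rho = 0.68, adjusted p = 8.67e-05; 0.62 in both). REL, a subunit of NF-kB, was correlated with its chromosomal neighbours BCL11A (r = 0.68, permutation p = 2e-05, adjusted p = 8.67e-05; rho = 0.76, adjusted p = 5.20e-05; 0.65 and 0.66) and with XPO1 (r = 0.56, permutation p = 9e-05, adjusted p = 3.25e-04; rho = 0.53, adjusted p = 0.0012; 0.53 and 0.61). With the mean of all probe sets of a gene, REL and XPO1 did not pass (r = 0.168). REL did not pass with the NF-kB target score (r = 0.10, permutation p = 0.521, adjusted p = 0.592; rho = 0.02; 0.13 and -0.11).

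**Figure D3:**
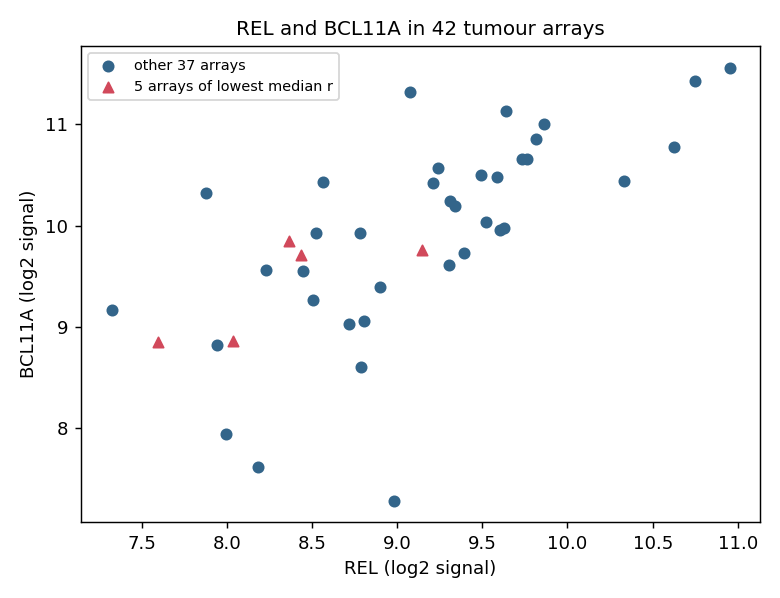
BCL11A against REL, both as log2 signal, in 42 arrays, each point 1 array, with triangles for the 5 arrays of lowest median r. BCL11A is higher where REL is higher, with r = 0.68 in all arrays and 0.66 in the other 37.

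B2M, the shared chain of MHC class I, followed the cytotoxic cell (r = 0.64, permutation p = 1e-05, adjusted p = 6.50e-05; rho = 0.64, adjusted p = 5.20e-05; 0.60 without the 2 farthest and 0.65 in the 37 arrays) and T cell scores (r = 0.63, permutation p = 2e-05, adjusted p = 8.67e-05; rho = 0.64, adjusted p = 5.20e-05; 0.61 and 0.69). Its relation to the cytotoxic cell score did not pass given the T cell, macrophage and stroma scores (r = 0.17). IRF4 followed PRDM1, both plasma cell regulators (r = 0.55, permutation p = 1e-04, adjusted p = 3.25e-04; rho = 0.42, adjusted p = 0.0140; 0.41 and 0.42). CDKN2A followed proliferation (r = 0.55, permutation p = 2.50e-04, adjusted p = 7.22e-04; rho = 0.44, adjusted p = 0.0087; 0.38 and 0.40), and did not pass with probe sets ending in _x_at left out (r = 0.249). The other positive relations were TNFRSF14 with the T cell score (r = 0.46), TNFAIP3 with PRDM1 (r = 0.46), MYC with MYC targets (r = 0.42) and FCGR2B with the macrophage score (r = 0.36). Their adjusted p ranged from 0.0046 to 0.0380 and their rho from 0.38 to 0.59. The relation of FCGR2B did not pass without the 2 farthest arrays (r = 0.33) or without the filter on dim genes. That of TNFAIP3 with PRDM1 did not pass given array quality and the 3'/5' ratio (r = 0.31) or given the T cell, macrophage and stroma scores (r = 0.20). The remaining 13 relations did not pass (adjusted p from 0.0749 to 0.976), among them CDKN2A with CDKN2B (r = -0.32) and with MTAP (r = 0.27), MYC with proliferation (r = 0.10), BCL6 with PRDM1 (r = 0.05) and MDM2 with CDK4 (r = 0.19). CD58 with the T cell score had an r of 0.24, and of 0.48 in the 37 arrays, where it passed.

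Genes of a gained or lost segment would vary together, so the mean pairwise r of 21 neighbouring tested genes was compared with 10000 windows placed at random, around 14 anchor genes. In this one-sided test 0 of 14 anchors passed, and 0 had an unadjusted p under 0.05. Shared variation weaker than a mean r of 0.36 was not simulated, so this does not exclude segments changed in some tumours. The highest values were those around FCGR2B (mean r = 0.109, p = 0.0729, adjusted p = 0.510), TNFAIP3 (0.101), MDM2 (0.090) and REL (0.081), against a median of 0.044 and a 95th percentile of 0.120 over the random windows. The window around CDKN2A had a mean r of -0.011, and those around PRDM1, MYC, TNFRSF14, B2M, RB1, BCL2, CREBBP, BCL6 and CD58 lay between -0.001 and 0.071.

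The most coherent window of all, on chromosome 19 from RAVER1 to TSPAN16 and including TYK2, KEAP1, DNM2 and SMARCA4, had a mean r of 0.320, and 0.084 in the 37 arrays, where the 95th percentile of windows was 0.120. This window and those named next were chosen after their values were seen. A cluster of histone genes on chromosome 6 (H3C2 to H4C8) reached 0.261, and the MHC class II region from PBX2 to HLA-DPB1 reached 0.224.

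**Figure D4:**
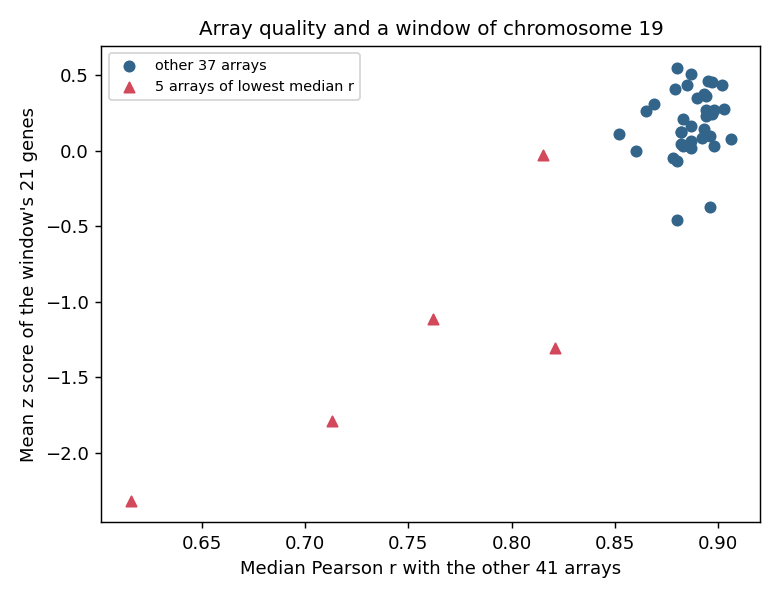
Mean z score of the 21 genes of the chromosome 19 window (vertical axis) against the median Pearson r of the array with the other arrays (horizontal axis), each point 1 of 42 arrays, with triangles for the 5 arrays of lowest median r. The triangles lie at the left, from a median r of 0.616 upward, and the window's mean r was 0.320 in all arrays and 0.084 in the other 37.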

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

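The test of the share of all other cells in all arrays, and the tests of the chromosome 19 window by gene order, array quality and the r with other windows, were set before their results were seen. The other tests in this part, random windows and random gene sets included, were chosen after the results were seen.

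A signal appeared outside the gene measurements: the cre hybridization control had a log2 signal of 14.25 in tFL tumour replicate 10 and at most 5.50 in the other 41 arrays, and bioB was 7.85 there and at most 4.82 in the others.

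More genes rose than fell along the proliferation score (72.7%) and the T cell score (79.2%). Without the 5 arrays of low correlation the percent rising was 58.4 and 60.7, while 50 random sets of 5 other arrays left out gave 71.7 to 77.7 and 72.9 to 93.2. Array quality is a candidate explanation along proliferation, where rising genes fell from 1477 to 897 in number. However, leaving out replicate 5 alone, the array of lowest proliferation score (-2.17), gave 656 rising genes (60.5% rising). The random sets never held this array. The test therefore cannot tell the quality of the 5 arrays from the pull of 1 array at the end of the score. Along the T cell score rising genes went from 838 to 1019 and falling genes from 220 to 659, so the lower percent does not show that the 5 arrays added rising genes. With the 3'/5' ratio as a covariate 1069 genes rose and 305 fell along proliferation (77.8% rising) and 833 rose and 171 fell along the T cell score (83.0%), so more genes still rose than fell, which argues against this ratio as the whole cause; no biological explanation was tested, since the design names no groups.

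The proliferation score was lower where the T cell score was higher (r = -0.42). Given array quality and the 3'/5' ratio r was -0.52 (permutation p = 4.20e-04), which argues against array quality as the whole cause, although given the 3'/5' ratio alone the correlation (r, proliferation with T cell, of -0.345) did not pass. Given the mean of the macrophage, follicular dendritic cell, stroma and endothelial scores r was -0.21 (permutation p = 0.184; rho = -0.33, p = 0.0359), between the bounds set in advance, and in the 37 arrays it was -0.34 (permutation p = 0.0401), past the bound against a lower share of tumour cells by less than its spread. Given the B cell score r was -0.39 (permutation p = 0.0107). The B cell score was only weakly correlated with the proliferation score (r = 0.22) and the T cell score (r = -0.26). Removing it could therefore change r only a little, and the value does not weigh against that share. The share cannot be told apart from a relation of T cells with proliferation because the value in all arrays meets neither bound, and no biological explanation was tested.

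The 21 genes of the chromosome 19 window varied together (mean r = 0.320). Of 1001 gene orders, the real one included, 1 held a window as high (the highest shuffled value was 0.270), which argues against chance order. After removing the proliferation, T cell, macrophage, stroma and B cell scores the mean r was 0.251. This argues against what these 5 scores measure as the whole cause. Scores of other cell types were not removed. After removing array quality and the 3'/5' ratio the mean r was 0.083, under the 95th percentile of windows (0.108), so array quality may account for the pattern. Array quality here is the median correlation, which comes from the same values. Removing it can also take out shared variation of other sources, so the fall is no independent evidence of a quality cause. The window's mean had a median r of 0.66 with the 5 other highest windows of chromosomes 1, 7, 9 and 16. Single values ranged from -0.15 (chromosome 7) to 0.89 (chromosome 9). In 1000 random draws of 5 windows, the median r of a draw had a median of 0.30 and a 95th percentile of 0.53. These bounds apply to medians of 5 windows and not to the single values. Given array quality and the 3'/5' ratio the median was 0.11, with -0.48 for chromosome 7 and 0.56 for chromosome 9. The median of 0.66 met the bound set in advance for an effect shared by gene-dense regions. The random draws and the median given array quality and the 3'/5' ratio were not part of that bound. Gene density was not measured, so an effect of gene-dense regions stays open, and no biological explanation was tested.

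Shuffling a score over the arrays gave at most 273 genes against 2035 for proliferation, 1 against 397 for activated minus germinal centre B cell, and 2 against 1058 for the T cell score, with all genes fitted against the whole score. Each score is made of genes of the same arrays, so a shuffled score has to do worse, and this does not exclude chance. Scores of random gene sets gave at least as many genes in 45, 32 and 46 of 100 sets, so the counts do not set the fixed scores apart.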

How the results depend on the processing

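The alternatives without the 5 arrays of low correlation, without the array of high cre signal, with array quality as a covariate, and leaving out each array were chosen after seeing the data. Where a count moved by over 1.5 times, the cause was not tested beyond the fewer arrays or added covariates of the alternative. Without the 5 arrays, 897 genes rose with proliferation, 290 fell with the activated minus germinal centre B cell score, 659 fell with the T cell score, and 13 lists shifted down along proliferation and 2 along activated minus germinal centre B cell. With array quality and the 3'/5' ratio as covariates 890 genes rose with proliferation and 548 with the T cell score, and with the 3'/5' ratio alone 305 fell with proliferation. Without the 2 farthest arrays 545 rose and 345 fell with proliferation, 351 rose and 31 fell with the T cell score, and 21 list pairs were positively correlated. With the T cell, macrophage and stroma scores as covariates 96 genes rose and 108 fell with the activated minus germinal centre B cell score, 9 list pairs were positively and 3 negatively correlated among those without these lists, and r of the cytotoxic cell with the interferon response score turned to -0.114. With an estimated correlation 0 lists shifted up and 0 down along proliferation and along activated minus germinal centre B cell, and 2 up and 0 down along the T cell score. Leaving out each array in turn gave totals of 1085 (without replicate 5) to 2359 genes for proliferation, 297 to 516 for activated minus germinal centre B cell, and 691 (without replicate 30) to 1426 (without replicate 5) for the T cell score. Of the slopes of the 12 largest rising and falling genes, 986 alternatives kept direction and call and 86 lost the call. Of the correlations, 1100 alternatives kept the call or stayed without one, 93 lost the call and 49 gained it. Direction was compared only where the correlation in all arrays had passed. Some that had not passed changed sign, for example BCL6 with PRDM1 (r = 0.05, and -0.26 in the 37 arrays). In the window test no anchor had passed, and all 168 alternatives kept that outcome. Median, mean and test differed in sign for the epithelial list along proliferation, the p53 target list along activated minus germinal centre B cell, and the lymphoma and erythroid lists along the T cell score. No paired analysis was possible because the labels give a single group. Signals near the floor of 3.33 have no order.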

Other observations

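The array means of the marker lists differed in their spread between arrays. Mean signals come from different probe sets and cannot be compared between lists as expression levels. MHC class II genes had a mean log2 level of 11.36 ± 0.68 (SD over 42 arrays), MHC class I genes of 10.99 ± 0.45 and oxidative phosphorylation genes of 11.26 ± 0.27, the smallest spread of any list. Erythroid genes (5.94 ± 1.45), stroma genes (9.17 ± 1.31) and follicular dendritic cell genes (8.79 ± 1.26) had the largest spreads. Epithelial genes averaged 5.06 ± 0.70 and adipocyte genes 5.52 ± 1.17.

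The tests of this part were chosen after the results were seen. Among the 276 pairs of the 24 most variable genes, 4 were positively and 1 negatively correlated past the threshold by Pearson's r, 3 of them also by Spearman's rho. ORM1, an acute phase protein, followed the macrophage chitinase CHIT1 (r = 0.73, permutation p = 1e-05, the smallest that can be given, adjusted p = 9.20e-04; rho = 0.71, adjusted p = 0.0028; r = 0.74 without the 2 farthest arrays and 0.74 in the 37 arrays). FABP4, expressed by adipocytes, followed SFRP4, a secreted Wnt inhibitor (r = 0.61, permutation p = 1e-05, adjusted p = 9.20e-04; rho = 0.64, adjusted p = 0.0028; 0.57 and 0.67). RARA, measured by the probe set that stands apart from the gene's others, followed ZNF595 (r = 0.64, permutation p = 1e-05, adjusted p = 9.20e-04; rho = 0.58, adjusted p = 0.0083; 0.56 and 0.45). IGHM and LTF (r = 0.53, adjusted p = 0.0132; rho = 0.42, adjusted p = 0.162) and HLA-DRB4 and HLA-DQA1 (r = -0.56, adjusted p = 0.0132; rho = -0.45, adjusted p = 0.162) passed by r and not by rho.

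The mean of 965 tested genes elsewhere on chromosome 19 had an r of 0.85 with the mean of the chromosome 19 window, where 1000 random sets of as many genes of other chromosomes gave a median of 0.77 and a 95th percentile of 0.83.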
